A study of Mus musculus with 3 samples.

How the data were processed

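Total RNA sequencing after ribosomal RNA depletion was performed on the cytosolic fraction of bone-marrow-derived macrophages, in 3 libraries of 1 group, per the labels. Replicate numbers were those of the labels. The labels list separate biological samples under the same donor entry and do not say whether the cultures came from different animals, so tests over libraries measure the spread between these samples.

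Each library had a gene table and 2 transcript tables on genome build mm10 with the GENCODE M21 annotation, per the text deposited with each library. Expected counts per gene and per transcript were deposited by the authors from a transcriptome alignment, per the file headers and that text. TPM values were computed by the authors per kilobase of effective length and scaled to a fixed total over genes, numbered tRNA entries and control sequences, per the file headers. The percent of a gene's abundance in each transcript was given by the authors, per the file headers, and the shares reported here were computed from transcript TPM. A second set of transcript tables was made directly from the reads, in another column layout, with its own estimated counts and TPM, per the file headers. The aligner, the quantification tools, their versions and the strand setting are not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart. TPM depends on the effective length of short RNAs, so the large share of 7SL RNA lowers the TPM of every other gene, and a library with more small RNA shows lower TPM for messenger RNA.

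All 55536 genes in the tables matched the annotation used here, which is of the same release, and coordinates were taken from it. Entries that are not genes (96 control RNAs of the ERCC set, 26248 numbered tRNA entries and the phiX control) were left out of totals and tests. They held 0.3783%, 0.0931% and 0.0772% of counts in replicates 1, 2 and 3, nearly all phiX. A symbol shared by several genes was resolved to the gene with the highest mean TPM, which applied to 118 symbols. Expected counts on genes totalled 50807046, 53364168 and 46546422 in replicates 1, 2 and 3, so 3 counts correspond to 0.059, 0.0562 and 0.0645 CPM.

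Levels were tested with limma 3.58.1 in R 4.3.3 by an intercept-only model of log2(TPM + 1) against the value at 1 TPM, with a mean-variance trend and robust moderation, for genes with TPM above 0 in at least 1 library. Benjamini-Hochberg adjusted p under 0.05 placed a gene above or below the level. The pseudocount of 1 compresses differences among low genes. List differences were tested by permuting list membership over genes (100000 resamples, two-sided), with genes in both lists left out and adjustment over 14 pairs. The range of each of 29 lists between libraries was set beside 10000 random lists matched in 20 bins of mean expression, as a description of these libraries. Variation beyond sampling noise was tested per gene by a chi-square test (2 degrees of freedom) on expected counts rounded to whole numbers, for genes with at least 30 counts in sum. The biological coefficient of variation was the square root of the common dispersion from edgeR 4.0.16 on rounded expected counts. Other computations used pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

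Gene lists, list pairs, tests and alternatives were fixed before the data were examined. The genes named were 20 preset key genes, the 3 highest and the lowest measured member of each list, the 10 highest genes, and the 5 genes with the largest SD of log2(TPM + 1) among those at a mean TPM of at least 10, 127 genes in all. Counts of list members by their highest or lowest library were chosen after the values were seen.

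The level test was tested on simulated data of 20685 genes. It recovered 80% of genes set 1.5-fold above 1 TPM, 68% of those set 1.5-fold below, and 100% at 2-, 4- and 8-fold, and called 3.5% of genes set at exactly 1 TPM. On 13064 simulated genes, the noise test called 100% of genes doubled in 1 library and 0.07% of genes with counting noise alone, and the estimated coefficient of variation was 14.8% for a true 15%. The list difference test called 6, 82 and 100 of 100 simulated lists at true log2 shifts of 0, 2 and 4. The list range passed the 95th percentile in 5, 48 and 50 of 50 simulated lists at shifts of 0, 0.3 and 0.6.

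Alternatives were a pseudocount of 0.1, a mean count of at least 10, a level of 5 TPM, the second set of tables summed to genes, TPM rescaled over nuclear protein-coding genes, TMM scaling, size factors from DESeq2 1.42.0, list medians, other count minimums, and leaving out each replicate. No comparison between groups was possible with 1 group, and untreated or once-stimulated cells were not analysed here.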

Results

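Gene expression was measured by total RNA sequencing in the cytosolic fraction of mouse bone-marrow-derived macrophages, cells grown out of marrow and widely used to study innate immune signalling. The cells had been exposed to lipid A at 100 ng/ml for 12 hours, kept without it for 12 hours, and exposed again at 100 ng/ml for 60 minutes. Lipid A is the part of bacterial lipopolysaccharide that the receptor Tlr4 recognises. The data comprised 1 group of 3 libraries, each made from 1 µg of RNA of a separate biological sample of strain C57BL/6J under the same donor entry. Expected counts on genes totalled 50807046 in replicate 1, 53364168 in replicate 2 and 46546422 in replicate 3. In the same order, 18066, 18183 and 18987 genes had a count. A gene without counts could have stood at up to 0.059, 0.0562 and 0.0645 CPM (counts scaled to a fixed total) in the same order, a limit of 3 counts that covers counting error only. With a single group, no untreated or once-stimulated cells were analysed here, so levels could not be set against a background, and the values below are levels, not responses. The questions open to these libraries were which genes stood above a fixed level, how gene groups compared within a library, and how far the replicates differed.

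In the gene tables, 7SL RNA took most of the TPM, while messenger RNA took most of the counts. The 7SL RNAs Rn7s1 and Rn7s2, the RNA part of the signal recognition particle, held 60.2% ± 3.04 (SD, n = 3) of TPM and 9.13% ± 1.47 of expected counts, and 22.5% ± 4.4 of TPM in the second set of tables. Protein-coding genes of the nuclear genome held 30.3% ± 3.69 of TPM and 88.2% ± 1.79 of expected counts. The 7SK RNA Rn7sk held 4.1% ± 2.36 of TPM, and Rpph1 and Rmrp, the RNAs of ribonucleases P and MRP, together held 4.03% ± 1.28. The ferritin genes Fth1 and Ftl1, which encode iron storage proteins, held 2.71% ± 0.227, with Fth1 at 19315 ± 1758 TPM (SD, n = 3) and Ftl1 at 7771 ± 607. The 10 highest genes, which also included Tmsb4x at 5034 ± 944 TPM, Ccl5 and Saa3, held 72.3% ± 3.27 of TPM and 14.8% ± 1.83 of expected counts. The copies Rn7s1 (chromosome 12, 69159295 to 69159594, mm10) and Rn7s2 (chromosome 12, 69361182 to 69361481) are nearly identical, so the division of reads between them is uncertain.

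**Figure D1:**
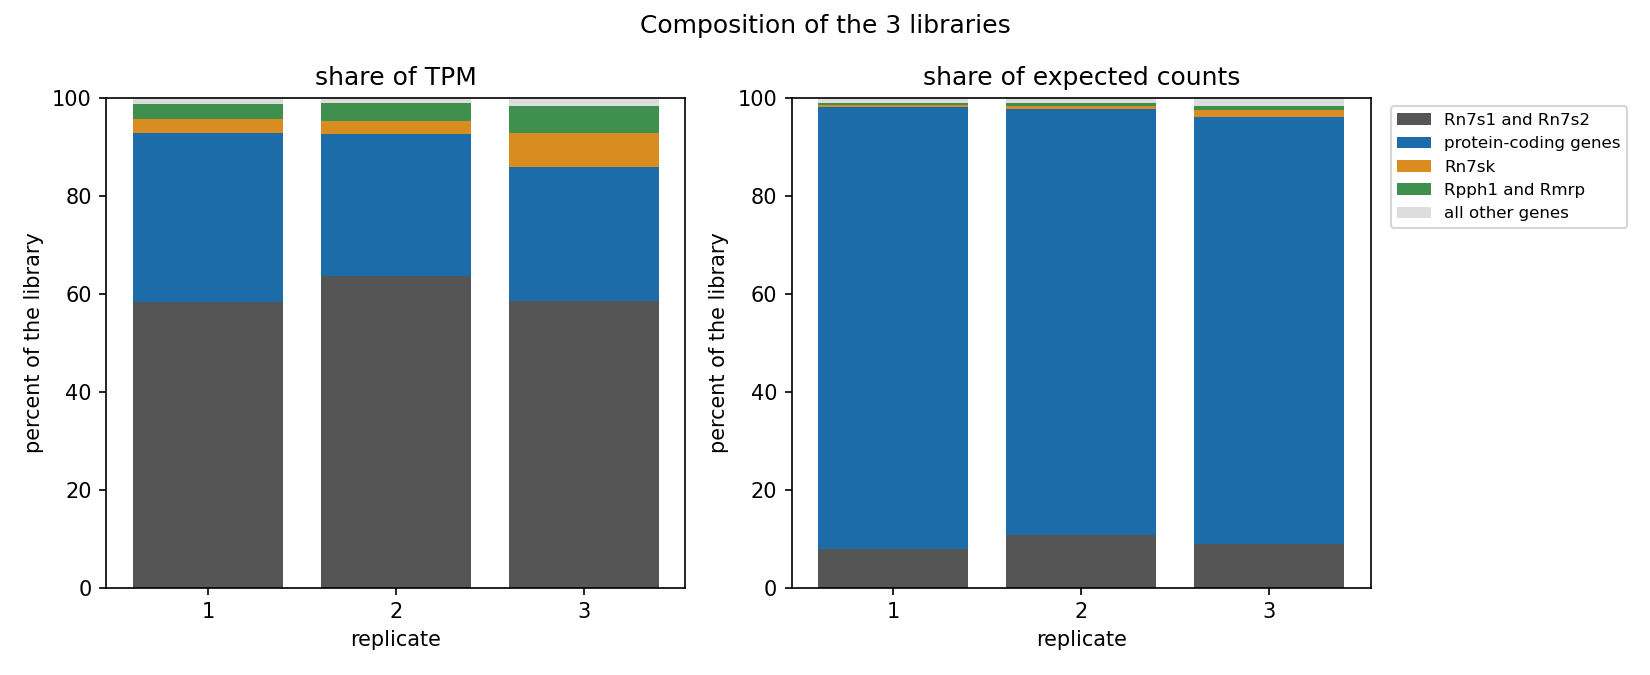
Stacked bars show the percent of each library (replicates 1 to 3) in named RNA classes, as a share of TPM in one panel and of expected counts in the other. The 7SL genes Rn7s1 and Rn7s2 hold 58.4%, 63.7% and 58.5% of TPM in replicates 1, 2 and 3.

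Of the 20685 genes with TPM above 0 in at least 1 library, 9195 stood above 1 TPM, 10435 stood below it and 1055 could not be placed (limma, log2(TPM + 1), Benjamini-Hochberg adjusted p under 0.05). A further 34851 genes were listed at 0 in all 3 libraries. Among the 424 distinct genes of the 29 lists, 300 stood above 1 TPM. The number above the level was 5491 at 5 TPM, and 3662 of 14374 coding genes stood below 1 TPM after TPM was rescaled over coding genes alone.

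Transcripts of the inflammatory response covered a wide range of levels. Tnf, a cytokine released early by macrophages, stood at 1206 ± 332 TPM (SD, n = 3; chromosome 17, 35199381 to 35202007), and the interleukins Il1b and Il1a at 305 ± 152 and 284 ± 112 TPM. Il6 was lower at 8.32 ± 4.36 TPM (chromosome 5, 30013114 to 30019981), and Il12b, a subunit of interleukin 12, stood at 4.75 ± 2.87 TPM, highest in replicate 2 at 7.94 TPM. Of 16 cytokine genes, 11 stood above 1 TPM and 4 below it, and Lif was the lowest at 0.0433 ± 0.0306 TPM. Of 19 chemokine genes, 15 stood above 1 TPM, 3 below it and 1 was listed at 0. The highest were Ccl5 at 4962 ± 1453 TPM, Cxcl10 at 837 ± 575 and Ccl4 at 786 ± 405. The list of inflammatory mediators, which shares members with both, had 14 of 17 genes above 1 TPM (11 in the second tables). They included the inducible nitric oxide synthase Nos2 at 3.61 ± 1.79 TPM and the interferon gene Ifnb1 at 5.64 ± 3.89 TPM, highest in replicate 1 at 9.78 TPM, and Csf3 was lowest at 0.177 ± 0.0451 TPM. The adjusted p against 1 TPM was 1.8e-08 for Tnf, 0.0012 for Il6, 0.0047 for Il12b, 0.0034 for Nos2 and 0.018 for Ifnb1 (limma). For each list in the text, the count adjusted over the list alone was the same as that over all genes tested. Counts for the second tables, here and below, used the same 1 TPM. Named genes there had a median of 0.449 times their TPM in the gene tables. The level is therefore stricter there, and a lower count is not by itself a disagreement on expression.

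All 19 genes of NF-κB subunits and feedback stood above 1 TPM, led by the inhibitor Nfkbia at 530 ± 140 TPM (SD, n = 3; chromosome 12, 55489410 to 55492647), Tnfaip2 at 238 ± 114 and the deubiquitinase gene Tnfaip3 at 236 ± 74.3, with Cyld lowest at 10.8 ± 1.78. Of 20 early response genes, 18 stood above 1 TPM and 2 could not be placed. Zfp36, which encodes a protein that destabilises cytokine messenger RNA, stood at 527 ± 131 TPM, Klf6 at 254 ± 72.5 and Junb at 249 ± 33.0. Fosb, not placed, stood at 0.8 ± 1.01, with 0.11, 1.96 and 0.33 TPM in replicates 1, 2 and 3, so replicate 2 carries most of its mean. Of 14 negative regulators of cytokine or Toll-like receptor signalling, 12 stood above 1 TPM. Acod1, the enzyme that makes itaconate, stood at 680 ± 183 TPM, Socs3 at 199 ± 47.5, Dusp1 at 156 ± 37.8, the interleukin 1 receptor antagonist Il1rn at 44.7 ± 7.05 and Il10 at 29.6 ± 14.9. Sigirr was below 1 TPM at 0.283 ± 0.0751. All 22 Tlr4 pathway genes stood above 1 TPM (20 in the second tables). They included Cd14 at 199 ± 71.0 TPM, Irf5 at 62.9 ± 11.7, Myd88 at 55.9 ± 10.9, Tlr4 at 21 ± 4.94 and Tirap at 2.02 ± 0.327.

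All 25 interferon-stimulated genes stood above 1 TPM, with Ifit2 at 913 ± 369 TPM (SD, n = 3), the antiviral gene Rsad2 at 832 ± 379, the transcription factor gene Irf7 at 695 ± 216 and Oas2 lowest at 14.9 ± 5.11. Each of the 25 was highest in replicate 1, also under TMM scaling. Of 15 antimicrobial and recognition genes, 11 stood above 1 TPM, and the highest were the serum amyloid gene Saa3 at 4696 ± 1966 TPM and the lysozyme gene Lyz2 at 3525 ± 672. Lcn2 stood at 16.1 ± 5 and the cathelicidin gene Camp below 1 TPM at 0.127 ± 0.0306. All 14 antigen presentation genes stood above 1 TPM (13 in the second tables), with B2m at 3846 ± 798 TPM, H2-K1 at 2036 ± 385, H2-D1 at 1543 ± 188 and the class II transactivator Ciita at 1.47 ± 0.248 (0.745 in the second tables, below 1 TPM). The H2, Ifit and lysozyme genes have close relatives in the genome, so reads shared among them leave their levels uncertain.

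**Figure D2:**
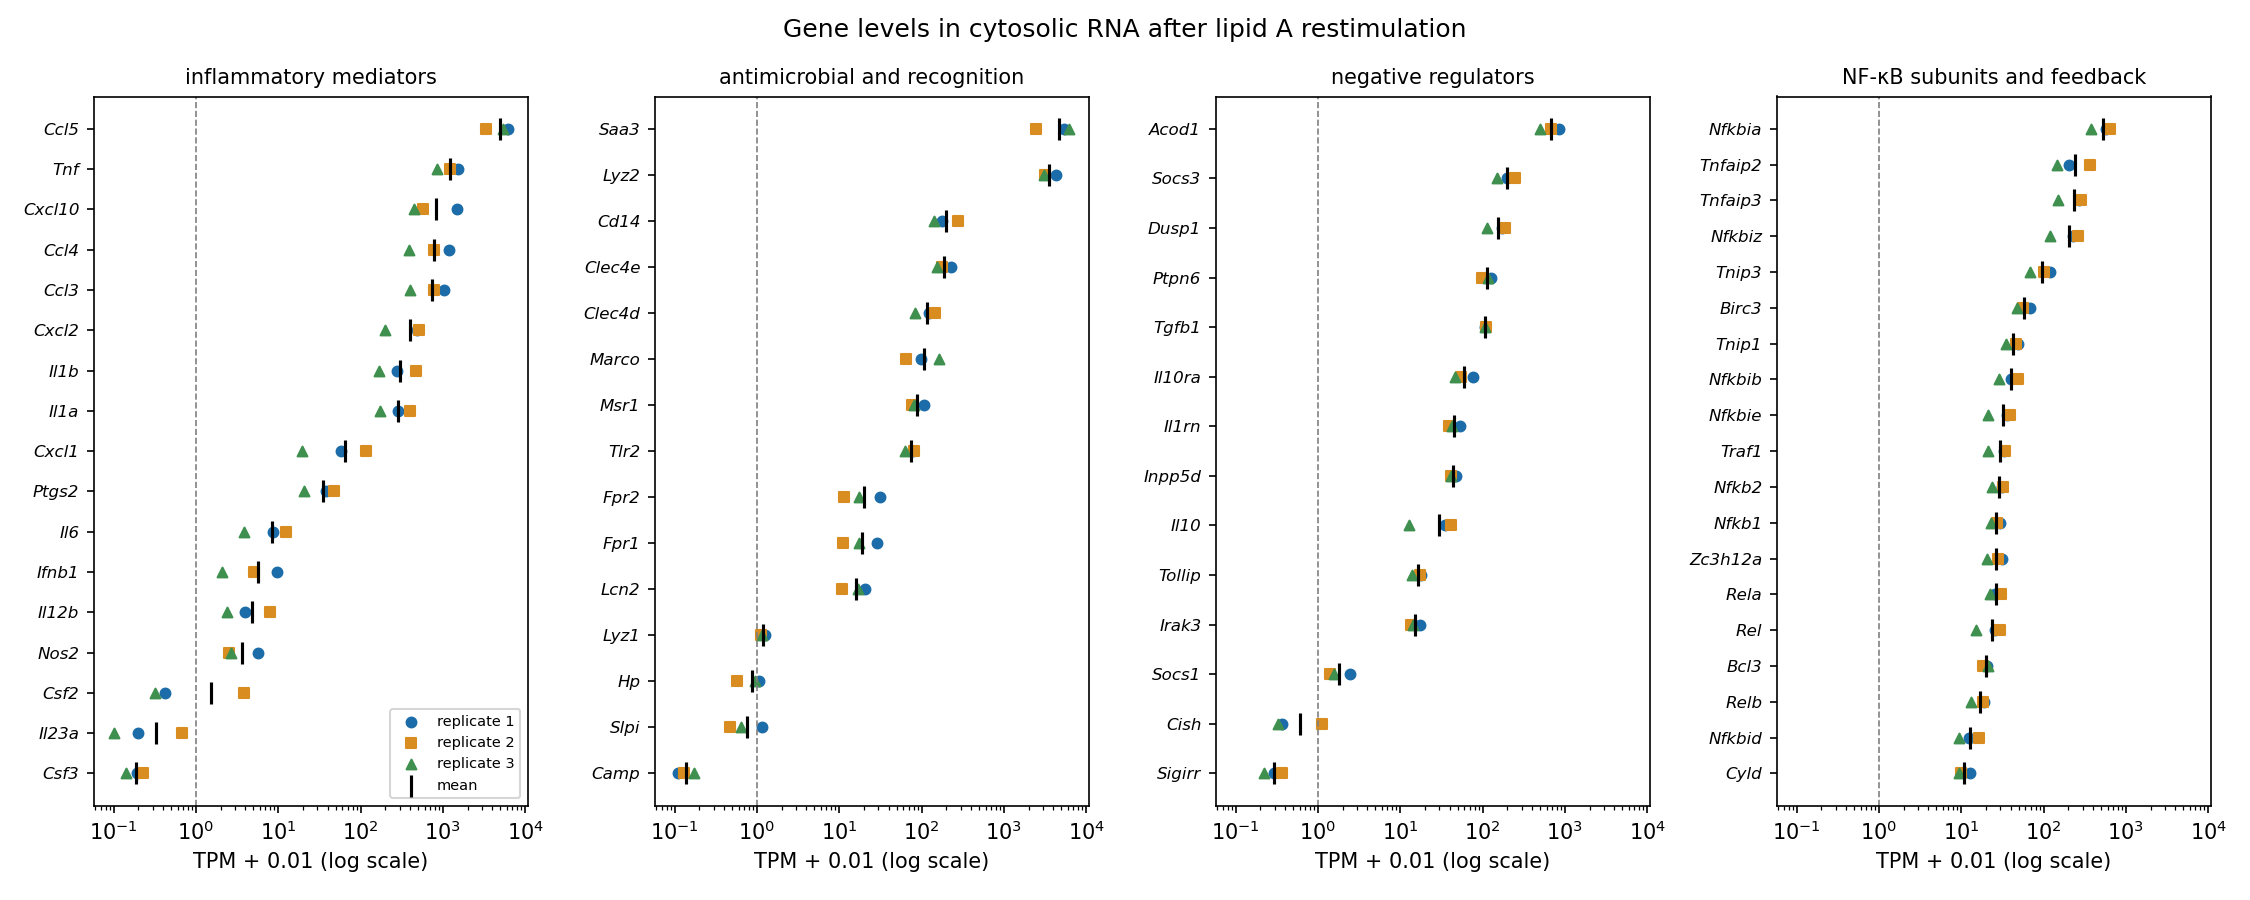
Points show the TPM (plus 0.01, log axis) of each gene in replicates 1, 2 and 3, with the mean as a vertical tick and a dashed line at 1 TPM, for 4 gene lists. Ccl5 and Saa3 lead their lists at 4962 and 4696 TPM, and all 19 genes of NF-κB subunits and feedback lie above the line.

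Markers of macrophages exceeded those of every other cell type examined. All 24 macrophage genes stood above 1 TPM. Among them were Lyz2 at 3525 ± 672 TPM (SD, n = 3), the lysosomal protease genes Ctsd at 2622 ± 137 and Ctsb at 2079 ± 372, Adgre1 (the F4/80 antigen) at 633 ± 127 and the growth factor receptor gene Csf1r at 138 ± 16.8, and Cebpa was lowest at 13.6 ± 2.68. The neutrophil list had 3 of 13 genes above 1 TPM (1 in the second tables), S100a9 at 4.66 ± 0.497, S100a8 at 3.14 ± 0.711 and Mmp8 at 1.85 ± 0.107 TPM. The T and NK cell list had 2 of 12, Cd28 at 27.6 ± 2.93 and Cd4 at 15.6 ± 3.77, while Lck stood at 0.0833 ± 0.0635. The B cell list had 1 of 11, Cd79b at 1.53 ± 0.346 TPM, and 0 without replicate 1, without replicate 3 or in the second tables. The dendritic cell, stromal, erythroid and mast cell or basophil lists, of 11, 12, 10 and 10 genes, had 0 above 1 TPM. Their highest genes were Batf3 at 1.42 ± 0.521, Col1a1 at 1.27 ± 1.27, Epor at 0.307 ± 0.0802 and Kit at 0.167 ± 0.102 TPM. The mean level of the macrophage list was higher than each of these lists by 7 to 7.72 on the log2(TPM + 1) scale, in 3 of 3 libraries. The differences were 9.41 to 10.82 with a pseudocount of 0.1, 8.39 to 9.36 after rescaling to coding genes and 6.09 to 6.66 in the second tables. For the main values, the SDs over libraries were 0.15 to 0.52, and each pair had adjusted p = 1.7e-05 (two-sided permutation test, 14 list pairs, raw p = 1e-05, the smallest that 100000 resamples give). With only genes at a mean count of at least 10, the difference from the T and NK cell list was 3.32 at adjusted p = 0.088.

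Transcripts linked to alternative activation were uneven. Of 14 such genes, 6 stood above 1 TPM (3 in the second tables), 5 below it and 2 were listed at 0. The transglutaminase gene Tgm2 stood at 38.5 ± 12.6 TPM (SD, n = 3), the interleukin 4 receptor gene Il4ra at 34.0 ± 10.8, the mannose receptor gene Mrc1 at 19.6 ± 4.73 and the arginase gene Arg1 at 0.0233 ± 0.0404, with 0 in replicates 1 and 2 (chromosome 10, 24915221 to 24927484). The macrophage list was higher than this list by 6.56 ± 0.13 on the log2 scale, in 3 of 3 libraries (permutation test, adjusted p = 1.7e-05, raw p at the smallest value the resamples give), after leaving out the shared gene Mrc1. The difference was 8.19 with a pseudocount of 0.1, 7.5 after rescaling to coding genes and 5.87 in the second tables.

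All 17 glycolysis genes (16 in the second tables) and all 18 citrate cycle genes stood above 1 TPM. In glycolysis, Gapdh stood at 353 ± 21.3 TPM (SD, n = 3), Aldoa at 156 ± 8.52, Pkm at 146 ± 3.71 and Slc16a3 at 2.44 ± 0.118. In the citrate cycle, Sdhb stood at 69.0 ± 1.97, Mdh2 at 51.8 ± 1.72, Sdha at 45.3 ± 4.46 and Suclg2 at 3.03 ± 0.196. Of 13 oxidative stress genes, 11 stood above 1 TPM, with Sqstm1 at 411 ± 137 and Nqo1 below it at 0.337 ± 0.0289. Of 12 sterol and lipid genes, 11 stood above it, with Apoe at 1068 ± 187, Plin2 at 170 ± 24.8 and Abcg1 at 64.0 ± 10.9. Ch25h, not placed, stood at 0.927 ± 0.737, with 1.77, 0.6 and 0.41 TPM in replicates 1, 2 and 3, so replicate 1 carries much of its mean. All 22 ribosomal protein genes stood above 1 TPM, led by Rps24 at 700 ± 106. The cell cycle list had 8 of 18 genes above 1 TPM, among them Pcna at 65.0 ± 5.01 and Mki67 at 10.5 ± 3.09, with Plk1 at 0.143 ± 0.0850, and the histone list had 9 of 14 (6 in the second tables), led by Hist1h2bc at 61.5 ± 12.0. Glycolysis genes were higher than citrate cycle genes by 0.82 ± 0.05 on the log2 scale in 3 of 3 libraries, a difference that did not pass the test over genes (permutation test, adjusted p = 0.18).

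Among functional groups, NF-κB subunit and feedback genes stood above Tlr4 pathway genes, by 1.52 ± 0.22 on the log2(TPM + 1) scale (SD, n = 3; higher in 3 of 3 libraries; permutation test, adjusted p = 0.0031). Early response genes stood below interferon-stimulated genes, by a difference of −1.91 ± 0.57 (higher in 0 of 3 libraries; permutation test, adjusted p = 0.0025). Inflammatory mediators and antimicrobial genes did not differ past the threshold, with a difference of 0.4 ± 0.57 (higher in 2 of 3 libraries; permutation test, adjusted p = 0.77), and the difference of medians had the opposite sign at −0.53. Cytokine genes minus negative regulators gave −1.11 ± 0.22 (permutation test, adjusted p = 0.35). These tests permuted genes, which are not independent replicates, and 3 libraries alone cannot go below an exact sign-flip p of 0.25.

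Non-coding RNAs retained in nuclei were detected in the cytosolic fraction, most of all in replicate 3. Malat1 stood at 112, 90.6 and 452 TPM in replicates 1, 2 and 3 (218 ± 203, SD, n = 3; chromosome 19, 5795690 to 5802672), Neat1 at 10.9, 7.1 and 29.7 TPM, and Rn7sk at 27778, 26912 and 68232 TPM. Of 10 nuclear non-coding genes, 3 stood above 1 TPM, 4 below it and 1 was listed at 0. Of 12 genes in the list named cytosolic non-coding, 10 stood above 1 TPM and 2 were listed at 0. That list includes Rmrp, at 5281, 4604 and 11846 TPM in replicates 1, 2 and 3, a rise in replicate 3 like that of the nuclear RNAs. Its place in the cytosol was not tested, and the list difference below depends on it in part. Shares of TPM in small nuclear, small nucleolar and small Cajal body RNAs in replicate 3 were 2.37, 2.36 and 2.44 times the mean of the others. The nuclear list minus the cytosolic list was −3.33 ± 0.46 on the log2 scale, with the nuclear list higher in 0 of 3 libraries (permutation test, adjusted p = 0.24). Mitochondrial messenger RNAs held 0.114%, 0.165% and 0.301% of TPM in replicates 1, 2 and 3. Of 13, 11 stood above 1 TPM, with mt-Atp8 at 656 ± 311, mt-Co1 at 467 ± 219 and mt-Co2, not placed, at 7.39 ± 6.41. While 11 of the 13 were highest in replicate 3, 2 were lowest there. One of these was mt-Co2, at 11.5, 10.7 and 0 TPM in replicates 1, 2 and 3. Reads of mitochondrial genes can be shared with nuclear pseudogenes and the overlapping annotations of Rmrp with each other, so those levels are uncertain.

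Replicates correlated closely across genes but differed in specific groups. Across 9774 genes at a mean TPM of at least 1, Pearson's r was 0.978, 0.977 and 0.979 for the 3 pairs, a correlation across genes, which are not independent replicates. Of 13075 genes tested, 9056 varied by more than sampling noise, and each pair of libraries alone gave 6389 to 6703, so no pair agreed within sampling noise. The biological coefficient of variation was 0.162 (edgeR common dispersion). Some of the 29 lists share members, so a count of lists is not one of independent groups. Of 50 simulated lists without a shift, 5 passed the 95th percentile of matched random lists. Negative regulators and histones stood only just past it, at percentiles 95.2 and 95.1. The range over libraries exceeded the 95th percentile of matched random lists for 12 of 29 lists. It was 1.35 on the log2 scale for mitochondrial messenger RNAs, 0.96 for inflammatory mediators, 0.9 for nuclear non-coding RNAs, 0.79 for interferon-stimulated genes (0.45 in the second tables), 0.76 for early response genes, 0.75 for chemokines, 0.72 for cytokines, 0.67 for stromal genes (2.13 with a pseudocount of 0.1 and 0.41 in the second tables), 0.59 for NF-κB feedback, 0.44 for antimicrobial genes, 0.4 for negative regulators and 0.34 for histones (0.52 with a pseudocount of 0.1). Without replicate 3, 5 lists exceeded it, and inflammatory mediators (0.05), NF-κB feedback (0.06), negative regulators (0.09), nuclear non-coding RNAs (0.16), cytokines (0.26), histones (0.27) and early response genes (0.29) no longer did. Without replicate 1, interferon-stimulated genes (0.11) did not. Antimicrobial genes did not without replicate 1 (0.18) or replicate 2 (0.27), nor histones without replicate 2 (0.08), while ribosomal protein genes exceeded it without replicate 1 (0.35). In the second tables antimicrobial genes (0.15) did not exceed it, while ribosomal protein genes (0.46) and oxidative stress genes (0.35) did. Ribosomal protein genes also exceeded it under TMM scaling (0.31), and negative regulators (0.45) did not with a pseudocount of 0.1.

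The groups deviated in different libraries. Relative to matched random lists, interferon-stimulated genes were higher by 0.3 on the log2 scale in replicate 1, and Cxcl10 followed with 1497, 574 and 441 TPM in replicates 1, 2 and 3. Inflammatory mediators, cytokines and early response genes stood 0.39, 0.37 and 0.4 above random lists in replicate 2 and at −0.53, −0.32 and −0.3 in replicate 3, where nuclear non-coding RNAs stood at 0.59. Mitochondrial messenger RNAs stood at −0.89 in replicate 1 and 0.76 in replicate 3 (−0.63 and 0.83 in the second tables). Of the 15 inflammatory mediators at a mean TPM of at least 1, 13 were lowest in replicate 3, under the deposited scaling and under TMM scaling alike. Low values there were not particular to them. Of 22 ribosomal protein genes, 21 were lowest in replicate 3 under the deposited scaling and 19 under TMM scaling. These ribosomal genes deviated less, at −0.11 from random lists. Of 24 macrophage genes, 8 were lowest in replicate 3 under the deposited scaling and 6 under TMM scaling. Other lists had more: 18 and 17 of 19 NF-κB genes, and 18 and 11 of 22 Tlr4 pathway genes, in the same order. Il1b stood at 280, 469 and 167 TPM, Il6 at 8.66, 12.5 and 3.8 TPM and Il10 at 34.5, 41.4 and 12.8 TPM in replicates 1, 2 and 3. The mediators did not all peak in replicate 2. Of the 15, 8 were highest there and 7 in replicate 1, among these Tnf at 1521, 1236 and 859 TPM. Stromal genes stood at −0.37 in replicate 1 and 0.34 in replicate 2, with Col1a1 at 0, 2.53 and 1.28 TPM and Col3a1 at 0, 2.03 and 0.77 TPM. The 5 most variable genes at a mean TPM of at least 10 were Gm24497, mt-Co3, Gm14303, Gm49369 and Gm25835, and mt-Co3 stood at 0.15, 18.5 and 150 TPM. Gm49369 (chromosome 7, 142371096 to 142382667) overlaps Ctsd, so its 13.2, 658 and 391 TPM are uncertain.

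**Figure D3:**
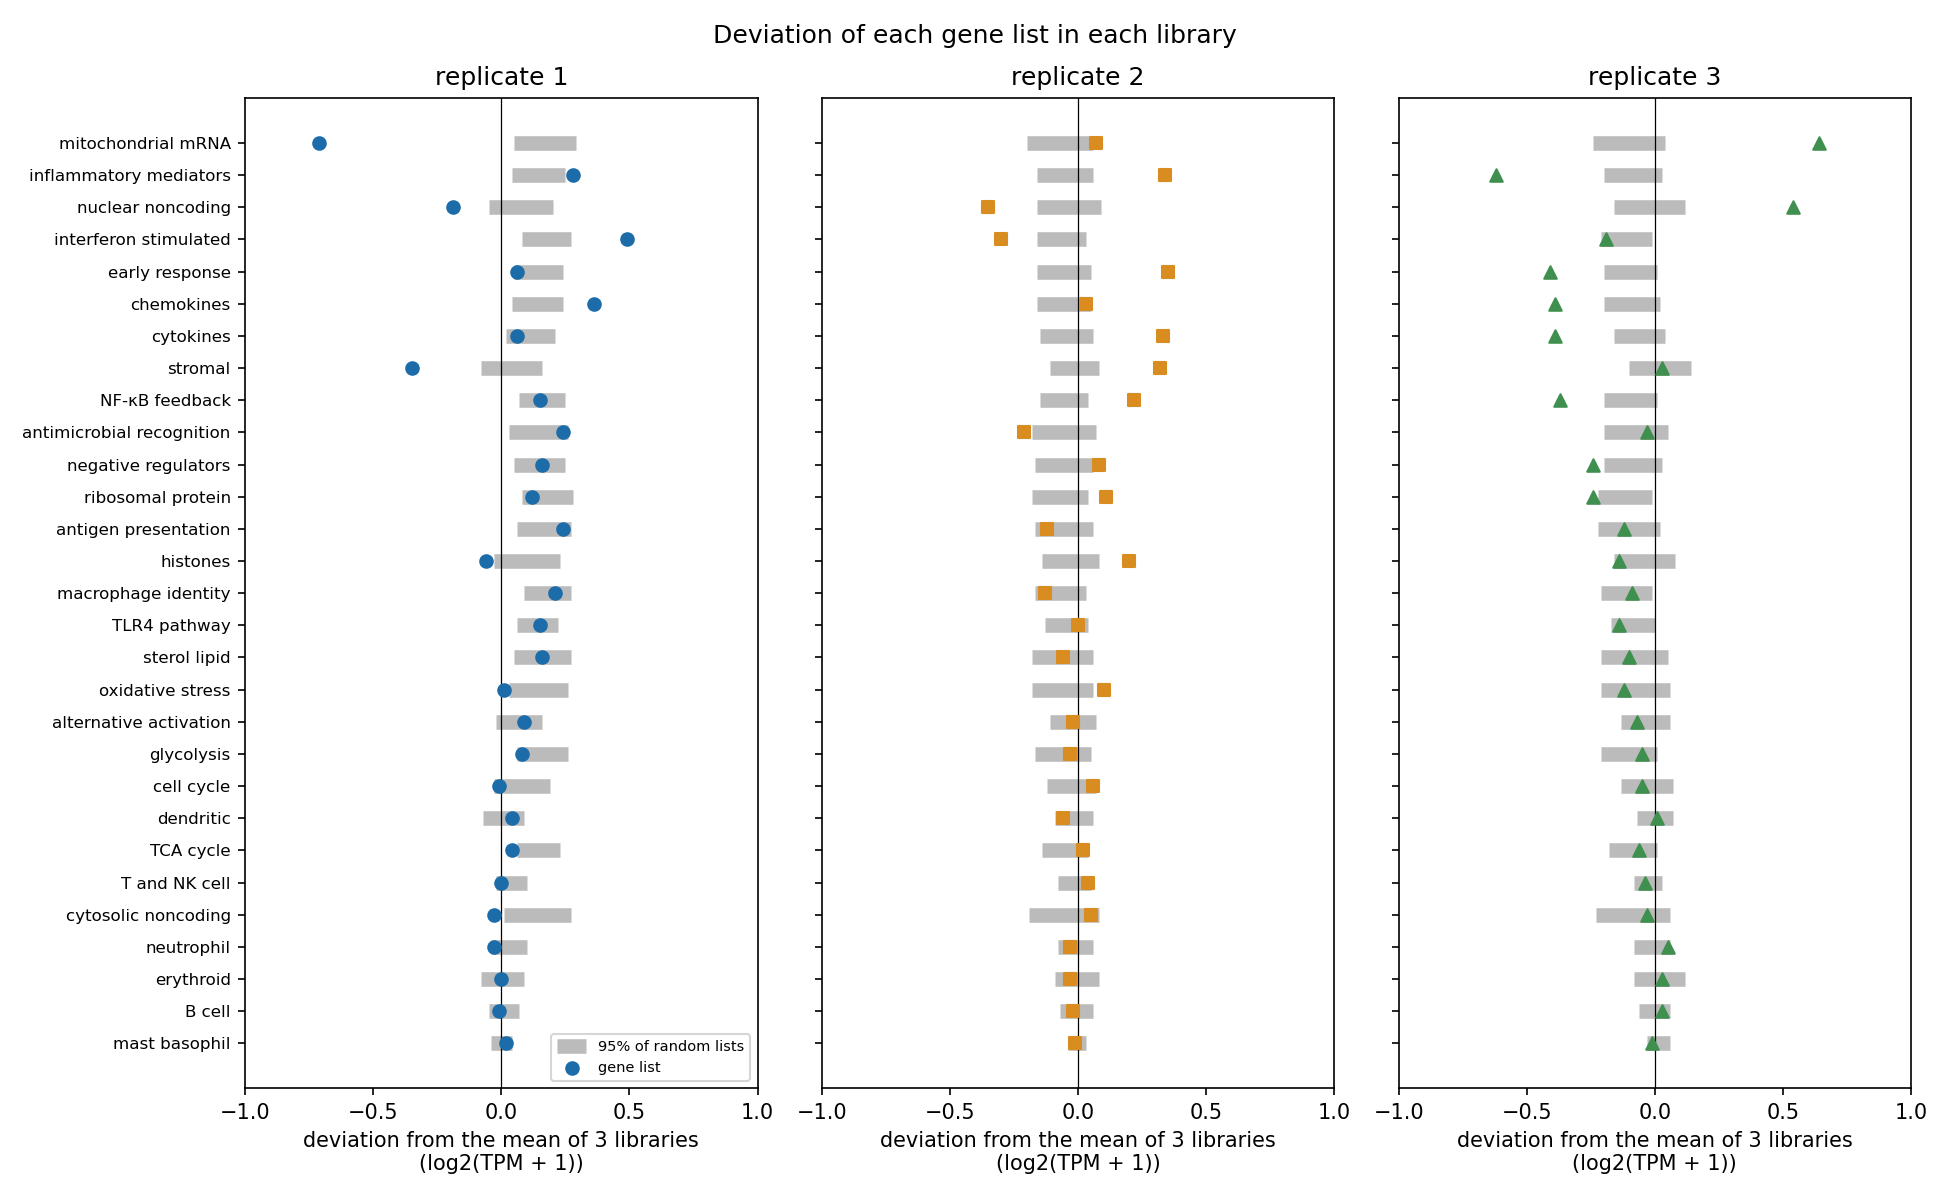
Points show how far the mean log2(TPM + 1) of each of 29 gene lists lay from its mean over the 3 libraries, and grey bars span 95% of 10000 random lists matched on mean expression. Interferon-stimulated genes lie above the bar in replicate 1, mitochondrial messenger RNAs lie below it there, and mitochondrial messenger and nuclear non-coding RNAs lie above it in replicate 3.

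The share of a gene's TPM in its main transcript differed among the key genes. The main transcript held 99.1% ± 0.414 (SD, n = 3) for Il1b, 99.7% ± 0.0691 for Nfkbia, 97.4% ± 0.706 for Tlr4 and 89.2% ± 0.824 for Cd14. Shares were lower for Tnfaip3 (85.0% ± 5.29), Il6 (83.9% ± 5.45), Adgre1 (78.0% ± 3.22), Il1rn (74.0% ± 1.64) and Malat1 (48.2% ± 4.45). Of 19 such shares, 10 were classed as moved in the second tables and 9 as the same. There, Tlr4 stood at 88.2% ± 8.09 and Il6 at 72.7% ± 8.3, while Adgre1 was close at 77.1% ± 2.62. For Csf1r, the transcript Csf1r-202 held 58.0% ± 16.1 in one set of transcript tables and 6.3% ± 1.78 in the other, where Csf1r-201 was the main transcript.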

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

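The tests of scaling for nuclear RNAs and for interferon-stimulated genes, and the test of depth for stromal genes, were chosen only after the result was seen.

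The phiX control sequence, outside the main measurement, took 0.3783% of counts in replicate 1, 0.0931% in replicate 2 and 0.0772% in replicate 3, above the limit that a count of 0 allows.

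Nuclear RNAs were higher in replicate 3, with Malat1 at 452 TPM against 112 and 90.6 TPM. For genomic DNA, 1135 olfactory receptor genes averaged 0.0174, 0.00833 and 0.0152 TPM in replicates 1, 2 and 3. Their mean was thus not highest in replicate 3, where Malat1 stood 351 TPM above the mean of the others. The preset mark, silent genes rising as much as Malat1, could not be met at a fixed TPM total. That comparison therefore could not decide on genomic DNA. Scaling was argued against, because the median log2 difference was 1.52 in the deposited TPM and 1.64 under TMM scaling. All 6 genes used, of 10 in the list, were higher. TMM shifts all genes of a library by 1 factor, here log2 −0.116, 0.036 and 0.08 in replicates 1, 2 and 3. The check therefore covers only a shift common to all genes. RNA of nuclei carried into the cytosolic fraction may account for the pattern. The share of transcripts with retained introns was higher in replicate 3 by a median of 0.23 on the log2 scale. The values were −0.14 and −0.18 for replicates 1 and 2. The bootstrap interval of the 0.23 was 0.21 to 0.25 over 3886 genes, which are not independent. The interval does not measure the spread between libraries. The 0.23 was only just past the preset mark, and 59.2% of the genes had their highest share in replicate 3. Mean shares were 4.93%, 5.04% and 5.55% in replicates 1, 2 and 3, and median shares 0.559%, 0.474% and 1.16%. Mitochondrial messenger RNAs, which are not nuclear, also rose in replicate 3, to 2.17 times the mean of the others as a share of TPM. Release of nuclear RNA inside the living cells was not tested.

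Interferon-stimulated genes were higher in replicate 1. Scaling common to all genes did not remove the difference. The median log2 difference was 0.72 in the deposited TPM and 0.54 under TMM scaling, and 25 of 25 genes were higher. TMM moves all genes of a library by 1 factor. The check covers only such a shift, which took away part of the difference. A stronger interferon response in that culture is a candidate explanation: in a further list written before its values were looked up, 34 of 34 measured genes were higher, with a median of 0.49. Ifnb1 stood at 9.78 TPM in replicate 1 against 5.09 and 2.06. Whether timing, cell density or the first exposure differed was not tested, and the genes respond to shared regulators, so they are not independent. The rise of the further genes extends the pattern. It cannot tell a stronger interferon response from another cause that moves these genes together.

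Stromal transcripts were higher in replicates 2 and 3, at 67.9 (95% interval 65.7 to 70.1) and 32.5 (30.8 to 34.1) CPM, against 1.06 (0.798 to 1.39) in replicate 1. Depth was argued against, since replicate 1 had more counts in all than replicate 3 (50807046 against 46546422) and fewer stromal ones (54 against 1511); the intervals cover counting error only. A small share of stromal cells in those cultures is a possible explanation that could not be settled: 11 of 16 further matrix genes were lowest in replicate 1, where more than 12 had been set as the mark, and Mmp2, Fbn1, Lox, Igfbp7 and Col4a2 were not. Among the most abundant stromal genes, Col1a1 reached 2.53 TPM and Sparc 1.91 TPM in replicate 2, and the osteoblast and adipocyte genes Bglap, Ibsp, Sp7, Alpl, Adipoq and Plin1 were at 0 in all 3 libraries, while Lpl stood at 86.8, 109 and 88.3 TPM and Runx2 at 0.62, 0.77 and 0.48 TPM in replicates 1, 2 and 3.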

How the results depend on the processing

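All alternatives here were planned, and none was chosen after the result was seen. No paired analysis was possible because there is 1 group of libraries. At a level of 5 TPM, 5491 genes stood above it. Genes above 1 TPM numbered 7771 in the second tables (7670 of the 9195 among them) and 10033 after rescaling to coding genes (8764 among them). Only nuclear coding genes were tested after rescaling. Of the 9195, 8775 were protein-coding, mitochondrial genes included, so the others had no test there. Genes below 1 TPM numbered 2953 at a mean count of at least 10, 19242 in the second tables and 3662 after rescaling to coding genes, where fewer or more genes were tested. Inflammatory mediators minus antimicrobial genes reversed to −0.53 with list medians (adjusted p = 1, against 0.61 to 0.98 under the others, permutation test), and the cause was not tested. Macrophage minus T and NK cell genes was 3.32 at a mean count of at least 10 (adjusted p = 0.088, against 1.6e-05 to 2.8e-05 under the others, permutation test), where 2 T and NK cell genes were left. Lists past the 95th percentile numbered 5 to 11 when one replicate was left out, with 5 without replicate 3. In the second tables, shares of TPM were 22.5% for 7SL RNA, 0.0895% for mitochondrial messenger RNA and 0.189% for ribosomal proteins. They were 1.58% for nuclear non-coding RNA, 27.4% for the 10 highest genes and 14% for coding genes. There, 5 short sequences at 0 in the gene tables took 59.7%. TPM sums to a fixed total, so this lowered the TPM of every other gene there. Why these sequences took that share, and whether it is the whole difference, was not tested. As shares of expected counts, nuclear non-coding RNA held 0.95%, the 10 highest genes 14.8% and coding genes 88.2%. Ciita and Cd79b were at 0.745 and 0.652 TPM in the second tables, below 1 TPM, and Tirap, Mmp8 and Snhg5 had means of 0.982, 0.896 and 0.956 TPM. Genes above 1 TPM there were 20 of the Tlr4 pathway, 1 of the neutrophil list, 3 of alternative activation, 13 of antigen presentation and 0 of the B cell list. With most TPM of the second tables on 5 sequences, 1 TPM is a stricter level there than in the gene tables. Fosb fell to 0.22 TPM without replicate 2. The biological coefficient of variation was 0.198 without a filter and 0.152 to 0.17 with one replicate left out. Besides Ciita and Cd79b, 94 of the 127 named genes moved by over 1 SD in the second tables, and 127 of 127 moved by less under TMM scaling. Lists of non-coding and mitochondrial genes have no value after rescaling to coding genes, and list pairs with under 2 genes left at a mean count of at least 10 have none there. Depth limits what can be said of genes near 3 counts.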

Other observations

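The ratios to Tnf below were chosen only after the result was seen.

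Tnf stood above Il1b, Il6, Il12b, Il10, Ifnb1 and Nos2 in each library, and was nearly equal to Cxcl10 in replicate 1, at a log2 ratio of 0.02. The log2 ratio of Tnf to Il6 was 7.3 ± 0.61 (SD, n = 3), a geometric mean of 158-fold, that to Il12b was 8.13 ± 0.73 and that to Il10 was 5.48 ± 0.59. Ratios to Il1b and Cxcl10 were smaller, at 2.07 ± 0.58 and 0.7 ± 0.59, and the ratio to Nos2 was 8.45 ± 0.45. A design of 3 libraries cannot pass an exact test at 0.05, the smallest p being 0.25. Without once-stimulated cells these ratios do not show which genes a first exposure had altered.

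The second set of tables put 59.7% of TPM on 5 short sequences, the pseudogenes Gm12895 and Gm12896, of 226 bases, and the annotated microRNAs Gm24245, Gm24270 and Gm23935, of 57 bases. Each pseudogene held 16.3% of TPM, while all 5 were listed at 0 in the gene tables. The median ratio of the second tables to the gene tables was 0.449 over 96 named genes at 1 TPM or more, and 95 of them were lower in the second tables. TPM sums to a fixed total, so the 59.7% on these 5 sequences lowered the TPM of all other genes there. Why the second tables placed that share on them was not tested, nor whether it accounts for the whole ratio.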
